A study of Mus musculus with 3 samples.

How the data were processed

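Gene expression was measured by RNA sequencing in T-helper 1 (Th1) primary cells of the mouse strain C57BL/6NJ. Th1 cells are the CD4 T-cell fate that makes interferon gamma. There were 3 libraries, which the labels number as biological replicates 1, 2 and 3 of 1 group and give the same donor record. The labels call the assay total RNA, while the linked library protocol is named for polyadenylated RNA. The file headers place the cells at 72 hours and call them sorted.

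The deposited values were raw counts of fragments per gene, 1 library per file, made with featureCounts 1.4.6-p4 per the file headers. The headers record that both ends of a fragment had to map, that exons were counted by gene on mm10 with GENCODE mouse release 13, and that the strand setting was 1, which counts a fragment when its first read lies on the strand of the gene. The folder named in the headers calls the libraries paired-end and stranded. The aligner's version was not given in the sources used here. The number of value columns not used was 0.

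Gene names and types came from GENCODE mouse release 21 on GRCm38, the same assembly as mm10, matched by gene identifier without its version. Of the 50600 genes in the files, 50376 matched and 224 did not. The genes without a match held 0.158%, 0.171% and 0.298% of the counts in replicates 1, 2 and 3. Coordinates are those of the deposited files, counted from 1. A gene was marked as having an opposite-strand overlap when any base of its exons lay in an exon of a gene on the other strand, which held for 8189 genes (16.2%).

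TPM, a length-scaled share of the library, was computed from the deposited counts and the deposited exon length of each gene. The design had assumed that TPM and expected counts would be deposited, so the deposited counts stood in for expected counts and posterior mean TPM was not used here. Means are over the 3 libraries with the sample SD. The text gives a gene below 3 counts as near the counting floor. For a gene of 2000 bp, 3 counts corresponded to 0.717, 11.6 and 0.737 TPM in replicates 1, 2 and 3. Intervals and floors cover counting error only, since fragments copied by PCR are not independent molecules.

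A protein-coding gene was called detected at a mean TPM of at least 1. Agreement between libraries was Pearson's r and Spearman's rho of log2(TPM + 1) across genes, which are not independent replicates. Genes varying between libraries were found with a chi-square test per gene on the counts, with TMM-scaled library sizes, a mean count of at least 10, Benjamini-Hochberg adjusted p under 0.05 and a ratio of highest to lowest library of at least 2, with a floor of 3 counts under the lowest library. That test compares libraries and holds counting error only. The biological coefficient of variation was the square root of edgeR's common dispersion. For 36 fixed gene pairs, limma's moderated test set the mean log2 ratio of TPM + 1 within each library against 0, two-sided, with Benjamini-Hochberg adjustment over the pairs. A sign-flip permutation test of 1 pair cannot go below 0.25 with 3 libraries. Adding 1 to TPM shrinks a ratio where a gene is low. In replicate 2, a gene with 0 counts enters as 0 TPM. There 3 counts in a gene of 2000 bp equal 11.6 TPM, so such a ratio can be overstated. For genes with no fragment, a fold was computed against 3 counts over the group.

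The Th1 list was compared with 15 lists of other T-cell fates and other cell types by a two-sided permutation test over genes on the difference of medians of mean log2(TPM + 1), exact or with 100000 resamples, with Benjamini-Hochberg adjustment. Genes in both lists were left out of the other list. For each list and library, the median difference from the mean of the other libraries was placed among 10000 random lists of the same size matched on mean expression. Members without a fragment were left out there, and 5 of the 30 lists had fewer than 3 members left.

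Lists, pairs, tests and the rule for named genes were fixed before the data were examined. The text may name every list member and every gene of the pairs. It also draws on the 15 protein-coding nuclear genes with the highest mean TPM, leaving out ribosomal protein genes, and on the 20 protein-coding genes past the test between libraries with the highest ratio. Alternatives changed the TPM minimum, the pseudocount, the filter on low values, the scaling (DESeq2 size factors, library totals, TMM-scaled CPM), medians against means, and left out each replicate. Added after the data were seen were a repeat on genes with no opposite-strand overlap, scaled over these genes alone, random lists matched on that overlap, and leaving out replicate 2 where this was not planned.

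The procedures were tested on simulated data. Of 100 genes changed 4-fold in replicate 3, the chi-square test recovered 100, and of 100 changed 2-fold it recovered 60, with 7 false calls among 11584 genes. These counts held Poisson error only. Changes in the shallower replicate 2 were not simulated. Of 9 simulated pairs with a log2 ratio of 3, limma recovered 9, and of 18 with a ratio of 0 it called 0. Those pairs were drawn from well-counted genes, with a biological coefficient of variation of 0.2 against 0.348 in the data. Of 1800 combinations of random lists and libraries, 89 fell outside the middle 95%.

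The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. No library was left out of the main results. Some genes of the lists and pairs are not reported here by name, and they remain in the counts and tests.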

Results

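RNA of 3 Th1 libraries was counted over 50600 genes. The total was 4482916 counts in replicate 1, 266790 in replicate 2 and 3733531 in replicate 3, so replicate 2 was 16.8-fold shallower than replicate 1 and 14.0-fold shallower than replicate 3. The chi-square value per degree of freedom over genes was 5.41 between replicates 1 and 2, 8.02 between 2 and 3 and 32.5 between 1 and 3, so the 3 files were not copies of each other. These values grow with depth, so they do not rank how alike the libraries were. They hold technical as well as biological differences. The labels number the libraries as biological replicates with 1 donor record, and of the p-values below only those of limma measure the spread between them. Genes with an opposite-strand exon overlap were 16.2% of the genes and held 51.7%, 55.1% and 66.5% of the counts in replicates 1, 2 and 3. A gene named below with such an overlap is marked as overlapped. Values are mean TPM ± SD (n = 3). Every level is that of the counted strand, which may be the strand opposite to the RNA, as set out in the last section.

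Among the 15 nuclear protein-coding genes with the highest mean, 9 were overlapped. The highest was Gm20721 at 12908 ± 1350 TPM, which shares 1469 exon bases with Gnas on the other strand. Others of this kind were Tlcd1 opposite to Rpl23a (2780 ± 207), Acat3 opposite to Tcp1 (2642 ± 259), Phykpl opposite to Hnrnpab (1942 ± 155) and Wdr38 opposite to Rpl35 (1910 ± 414). The 6 without an overlap were Eef1a1, the elongation factor that brings tRNA to the ribosome (4318 ± 1209), the chaperone Hsp90ab1 (3386 ± 823), the actin-binding Tmsb10 (2997 ± 607) and Tmsb4x (2124 ± 734), the nucleolar Npm1 (2293 ± 699) and the elongation factor Eef2 (1782 ± 554).

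At a mean of at least 1 TPM, 10408 protein-coding genes were detected, 3368 of them overlapped. Each library by itself held 10745, 8479 and 10471 such genes in replicates 1, 2 and 3. Across 13932 genes of any type, Pearson's r of log2(TPM + 1) was 0.915 between replicates 1 and 3, 0.801 between 1 and 2 and 0.767 between 2 and 3, and Spearman's rho was 0.914, 0.782 and 0.735. On 10854 genes with no overlap, scaled over these, r was 0.840, 0.759 and 0.710 in the same order. These are correlations across genes, which are not independent replicates.

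The question of the next comparison was how the genes of the Th1 fate stood against those of other fates. All 17 genes of the Th1 list reached 1 TPM and 13 reached 10 TPM. The cytokine lymphotoxin alpha, Lta, was highest at 1591 ± 483 TPM, followed by interferon gamma, Ifng, at 604 ± 252. The transcription factor Bhlhe40 (overlapped) had 203 ± 74.9, the interleukin 12 receptor chain Il12rb2 (overlapped, opposite to Serbp1) 140 ± 43.7 and the cytokine Tnf 110 ± 48.3. Tbx21, which encodes T-bet, the factor that sets the Th1 fate, had 70.5 ± 22.1 TPM. The interleukin 18 receptor chain Il18r1 had 71.3 ± 21.6, Runx3 38.5 ± 7.92 and Stat4, which relays interleukin 12, 24.0 ± 6.48. The chemokine receptors Cxcr6 (2.01 ± 1.92) and Cxcr3 (1.30 ± 1.16) were at the low end, and Cxcr3 had 8, 0 and 6 counts in replicates 1, 2 and 3. The mean of Cxcr6 was 1.11 without replicate 3. Without replicate 1 that of Cxcr3 was 0.851, and 16 of the 17 genes reached 1 TPM. Ifng lies on chromosome 10 from 118441046 to 118445892 and Tbx21 on chromosome 11 from 97098071 to 97115331 (GRCm38).

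Of the 13 genes of the Th2 list, 10 reached 1 TPM and 3 were below. Il24 was highest at 83.5 ± 27.7, then the chemokine receptor Ccr4 at 36.4 ± 32.1 and Ptgdr2 (overlapped) at 20.5 ± 2.51. The mean of Ccr4 was 18.4 without replicate 2, below the 21.9 of Ptgdr2. Gata3 (overlapped), the factor that sets the Th2 fate, had 2.19 ± 0.3 TPM, Il4 9.61 ± 2.96 and Il13 9.76 ± 8.79. Without replicate 1 the mean of Il13 was 6.11 and that of Il4 9.16. Il5 (overlapped) had 0 counts in each library. In the Th17 list 5 of 12 genes reached 1 TPM (3 of 12 without replicate 1) and 7 were below. Il23r, a receptor chain for interleukin 23, was highest at 25.1 ± 13.5, and Il17a had 0 counts in each library.

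The Treg list had 10 of 12 genes at 1 TPM or more and 2 below. Its highest members were Il2ra, the high-affinity chain of the interleukin 2 receptor (559 ± 166), the inhibitory receptor Ctla4 (325 ± 119) and Tnfrsf18 (overlapped, 231 ± 63.6), and T cells also express these on activation. Foxp3, the factor that sets the regulatory fate, had 64.9 ± 2.73 TPM, and its exons overlap those of Ccdc22 on the other strand. The Tfh list, of genes of follicular helper cells, had 7 of 10 genes at 1 TPM or more and 3 below. It was led by Cd200 (167 ± 64.6), Btla (106 ± 13) and Il21 (overlapped, 92.3 ± 12.5), while its factor Bcl6 (overlapped) had 0.842 ± 0.321.

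**Figure D1:**
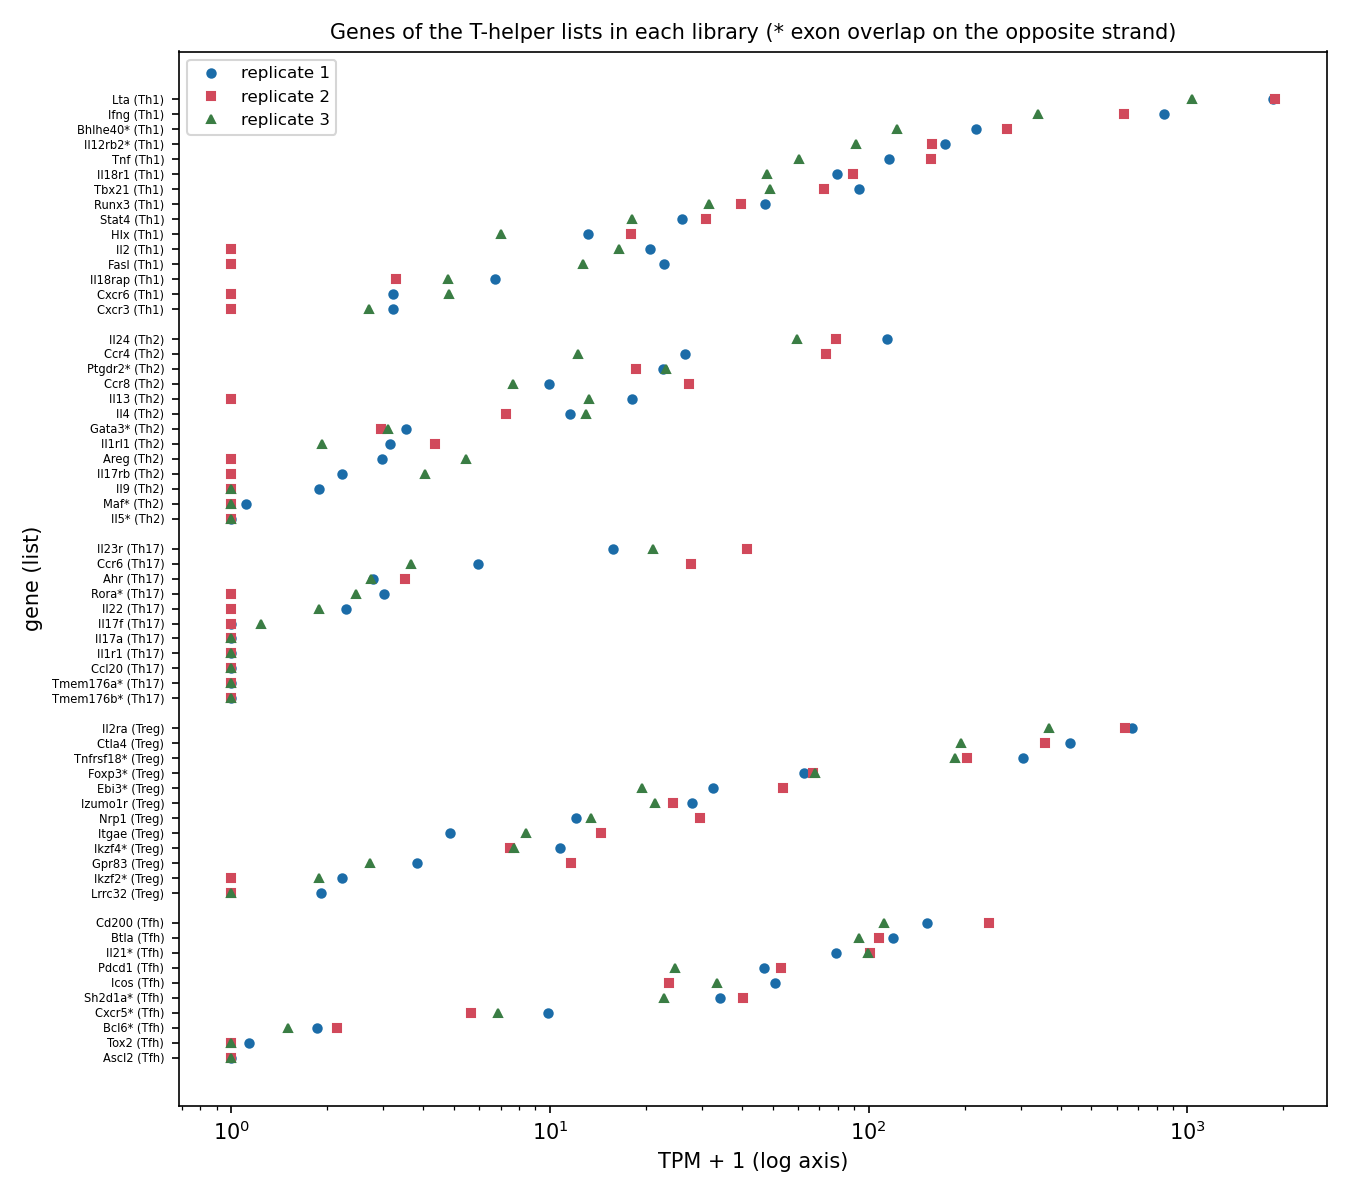
TPM + 1 on a log axis for the reported genes of the 5 T-helper lists, 1 point per library, with an asterisk at genes with an opposite-strand exon overlap. Lta and Ifng had means of 1591 and 604 TPM, while Il5 (overlapped) and Il17a had 0 counts in each library.

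By the permutation test over genes, the Th1 list was higher than 12 of the 15 lists compared. Besides Th2 and Th17, these were lists of other cell types, with medians from 0 to 0.445 on the log2(TPM + 1) scale. Those lists do not separate Th1 from other CD4 T-cell fates. The difference of medians on the log2(TPM + 1) scale was 2.96 against Th2 (permutation test, adjusted p = 0.0193) and 4.23 against Th17 (permutation test, adjusted p = 0.0132). Against Treg it was 0.29 (permutation test, adjusted p = 0.825) and against Tfh -0.41 (permutation test, adjusted p = 0.825), and against the 2 genes of CD8 T cells 3.93 (exact permutation test, adjusted p = 0.115). The difference from Th2 was 2.46 on genes with no overlap (permutation test, adjusted p = 0.155) and 3.18 without replicate 3 (permutation test, adjusted p = 0.0616). With members of at least 1 TPM alone, 0 of the 6 lists that could be compared passed, and 0 did at an unadjusted p under 0.05.

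Within each library, Th1 genes were set against matching genes of other fates in 36 fixed pairs, of which 32 passed limma's test. The first gene was higher in 25 and the second in 7. Tbx21 exceeded Gata3 (overlapped) by a mean log2 ratio of 4.44 (limma, adjusted p = 0.00014) and Bcl6 (overlapped) by 5.25, each in 3 of 3 libraries. Ifng exceeded Il4 by 5.78 (limma, adjusted p = 0.00014) in 3 of 3 libraries. Over the group, Ifng was at least 987-fold above Il17a and at least 1296-fold above Il5 (overlapped), both with 0 counts. Ifng had 5114 times the level of Il17f, which had 1 count, with a 95% counting interval from 917 to 202035. The T-cell coreceptor Cd4 was at least 816-fold above Cd8a, Il18r1 at least 576-fold above Il1r1, and the granule protease Gzmb at least 57.2-fold above Gzma, again with 0 counts in the second gene of each. Most of these counts were in replicate 1, and without it the bounds were 301-fold over Il17a, 395-fold over Il5, 312-fold over Cd8a, 227-fold over Il1r1 and 12.8-fold over Gzma, and Ifng had 1560 times the level of Il17f.

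The 7 pairs with the second gene higher included 3 of Cxcr3, which was below Ccr4 (-3.81), the lymph node homing receptor Ccr7 (-5.71) and Cxcr5 (overlapped, -1.82). Without replicate 2, where Cxcr3 had 0 counts, these ratios were -2.61, -5.31 and -1.49. Stat4 was below Stat6 (overlapped, -1.51) and Stat3 (overlapped, -1.28), and Il2rb was below Il2ra (-2.26), each in 3 of 3 libraries. Without replicate 1, the pairs of Stat4 with Stat6 (limma, adjusted p = 0.166) and Stat3 (limma, adjusted p = 0.186) and of Cxcr3 with Cxcr5 (limma, adjusted p = 0.0629) did not pass. Tbx21 against Foxp3 (overlapped) had a mean log2 ratio of 0.07 (limma, adjusted p = 0.856), with Tbx21 higher in 2 of 3 libraries. Runx3 against Zbtb7b (overlapped, 0.26) and Cxcr3 against Ccr6 (-2.04, and -0.66 without replicate 2) also did not pass. Of the 20 pairs in which neither gene was overlapped, 18 passed, and without replicate 1 the count was 26 of 36.

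**Figure D2:**
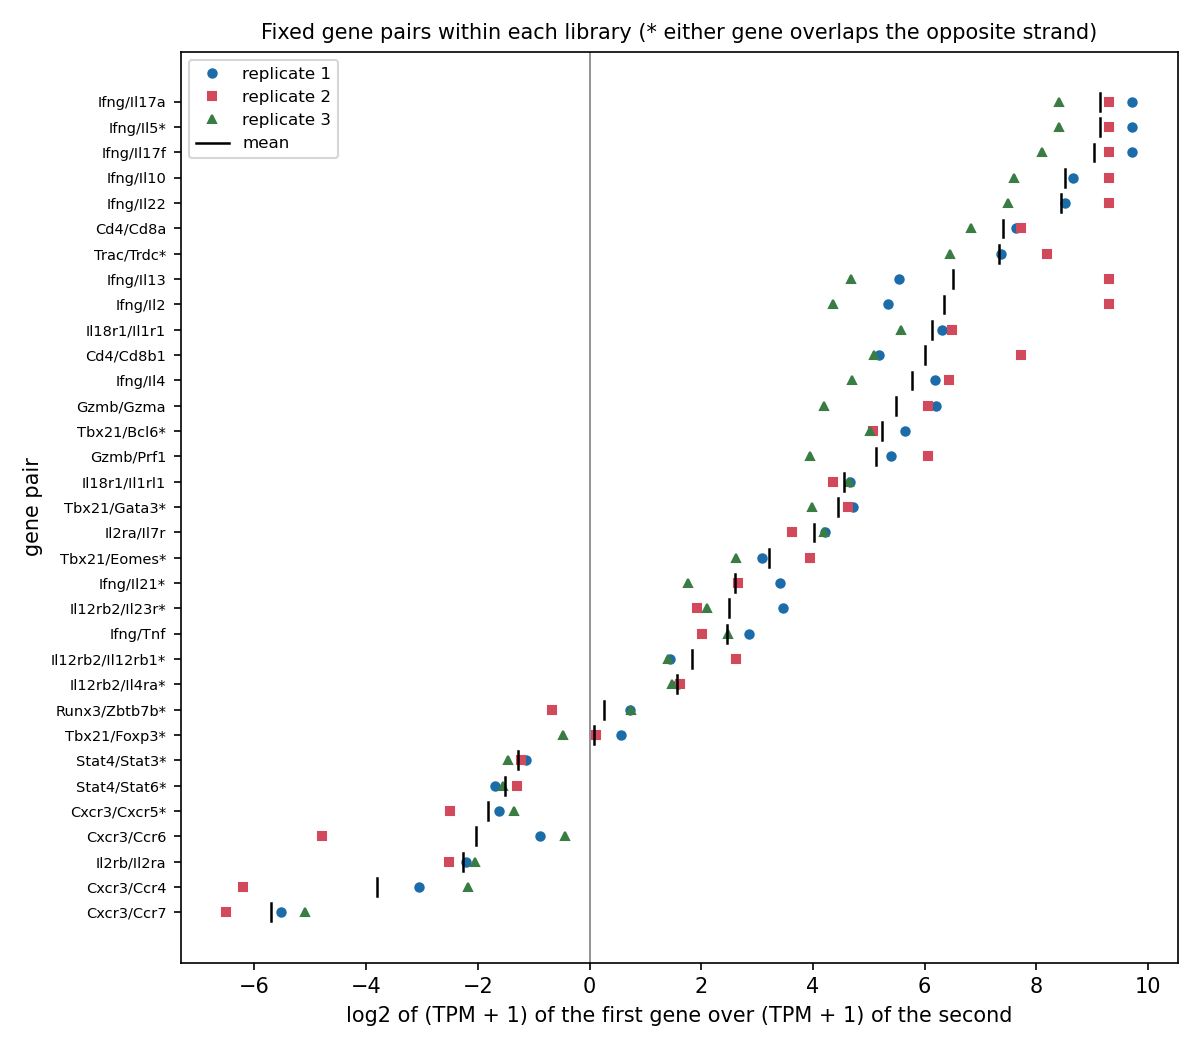
Log2 ratio of TPM + 1 of the first to the second gene of each reported pair, 1 point per library and a black bar at the mean, with an asterisk where either gene has an opposite-strand exon overlap. The means run from -5.71 for Cxcr3 over Ccr7 to 9.14 for Ifng over Il17a.

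Genes of T-cell identity and activation were counted in all libraries as groups. All 16 genes of T-cell receptor signalling had at least 10 TPM, led by the adhesion receptor Cd2 (436 ± 198), Cd5 (277 ± 62.2) and the receptor constant gene Trac (222 ± 81.3). All 12 activation genes reached 1 TPM, led by the costimulatory receptor Tnfrsf4 (342 ± 142), Cd40lg (273 ± 60.4) and the transcription factor Irf4 (210.5 ± 47.8). Of the 10 genes of naive or memory cells 9 reached 1 TPM, led by Ccr7 (109 ± 32.2) and Tcf7 (84.5 ± 26.5). Of the 8 inhibitory receptors 6 did (4 without replicate 1), with Lag3 at 61.3 ± 16.9 and Pdcd1 at 40.6 ± 15. Of the 13 cytotoxic genes 4 did, with Gzmb at 51.8 ± 30.0 and Nkg7 at 23.8 ± 15.7 (15.8 without replicate 1). All 16 cytokine receptor genes did, with Il2rb at 114 ± 28.0 and Il21r at 111 ± 24.1 below Il2ra.

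All 25 cell cycle genes reached 1 TPM and 24 reached 10 TPM. The highest were the cyclin Ccna2 (overlapped, 204 ± 49.5), the proliferation marker Mki67 (169 ± 36.1), the replication clamp Pcna (165 ± 62.4) and Rrm2 (153 ± 60.6). All 15 glycolysis genes had at least 10 TPM, led by lactate dehydrogenase Ldha (909 ± 267; no overlap), Tpi1 (overlapped, 662 ± 202) and Pkm (617 ± 195). All 14 genes of the TCA cycle and respiratory chain did as well, led by the ATP synthase subunits Atp5b (503 ± 146) and Atp5a1 (318 ± 100).

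Of the interferon gamma response list 15 of 16 genes reached 1 TPM, led by the GTPase Igtp (205 ± 46.9) and the immunoproteasome subunit Psmb8 (overlapped, 151 ± 46.8). Of the 12 type I interferon genes 7 did (5 without replicate 1), with Bst2 at 232 ± 65.4 and Isg15 at 46.7 ± 7.26. Rsad2 had 0 counts in each library. Among immediate early genes 9 of 10 reached 1 TPM, led by Junb (overlapped, 416 ± 91.9) and Ier2 (60.2 ± 31.4). Fos had 1.45 ± 1.58, and 0.610 without replicate 3. Of the p53 response list 9 of 10 reached 1 TPM, led by the cell cycle inhibitor Cdkn1a (211 ± 51.3) and Ccng1 (131 ± 52.9). All 10 genes of endoplasmic reticulum and amino acid stress did, led by Atf4 (365 ± 129) and the chaperone Hspa5 (329 ± 97.7).

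Markers of other cell types were mostly near the counting floor. Of 75 genes in 11 lists, 64 were below 1 TPM and 45 had 0 counts in each library, among them the macrophage gene Lyz2 and the platelet gene Pf4. The 6 genes above 5 TPM were Csf1r, a receptor of macrophages (111 ± 25.0), the immunoglobulin gene Ighm (23.1 ± 23.2), Cd68 (12.7 ± 5.15), the erythroid gene Alas2 (11 ± 10.2), Cd79a (8.23 ± 4.00) and Eomes (6.87 ± 3.09). Of these, Csf1r, Alas2 and Eomes were overlapped, and Csf1r lies opposite to Hmgxb3. Without replicate 2 the mean of Alas2 was 5.16, and without replicate 1 that of Ighm was 10.3. Below 1 TPM were 5 of 8 B-cell genes, 10 of 12 of macrophages, 6 of 7 of dendritic cells, and 8 of 8 of neutrophils, where Ly6g was highest at 0.860 ± 0.793. The same held for 6 of 7 genes of natural killer cells, 5 of 5 of mast cells (highest Kit, 0.0537 ± 0.093) and 6 of 6 of gamma-delta T cells (highest Sox13, 0.712 ± 0.621). It held for 6 of 7 erythroid genes, 4 of 5 of platelets (highest Gp1ba, 3.76 ± 1.76) and 7 of 8 of stroma, endothelium or epithelium (highest Pecam1, 4.58 ± 1.46). Zbtb46 was the highest dendritic cell gene at 1.04 ± 0.686, and without replicate 2 its mean was 0.653 and 0 of the 7 reached 1 TPM. Without replicate 2, 1 neutrophil gene and 1 gamma-delta T-cell gene did. Of the CD8 T-cell genes Cd8b1 had 2.28 ± 2.26, with 1.16 without replicate 1, and Cd8a 0 counts.

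The replicate libraries differed in many genes by more than counting error. Of 11595 genes tested, 3731 (32.2%) passed the chi-square test with a ratio of at least 2. Of the 2019 overlapped genes among them, 69.5% were highest in replicate 3, against 13.5% of the 1712 genes without overlap. Among the 20 protein-coding genes with the highest ratio, 15 were highest in replicate 2, on 7 to 14 fragments there. Tnni3, a heart troponin, led with a ratio of 23.2 (18, 10 and 5 counts), and Hacd1 had 19.9 (19, 12 and 7 counts). The reverse was Mgme1 (overlapped), with 497, 3 and 668 counts, and Akap8, with 621, 2 and 305. The count of genes was 1824 of 12257 tested (14.9%) without replicate 2, 1941 of 10804 (18.0%) without replicate 1 and 1332 of 11272 (11.8%) without replicate 3. On genes with no overlap it was 1201 of 6933 (17.3%), and 382 of 7414 (5.15%) when replicate 2 was left out as well. The biological coefficient of variation was 0.348, and 0.256 on genes with no overlap.

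Of 75 combinations of gene list and library, 9 fell outside the middle 95% of random lists, where chance gives 3.75. The Th1 list was lower in replicate 3 than in the other libraries by a median of -0.81 on the log2 scale (percentile 0.37), and T-cell receptor signalling genes by -0.69 (percentile 1.8). Glycolysis genes were higher in replicate 1 by 0.66 (percentile 99.9) and activation genes by 0.66 (percentile 99.8). With random lists matched on overlap, 5 of 75 fell outside. On genes with no overlap, scaled over these, the percentile was 11.3 for the Th1 list and 47.0 for T-cell receptor signalling in replicate 3, and 84.7 for glycolysis and 95.8 for activation in replicate 1. There 1 of 72 combinations fell outside, and it was the activation list in replicate 2 (-0.44, percentile 1.24).

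By gene class, protein-coding genes other than ribosomal protein genes held 71.6% ± 4.30 of the counts and long noncoding RNA genes 17.1% ± 4.62. All class shares are those of the counted strand. The long noncoding share may therefore hold fragments of coding genes on the other strand, as set out in the last section. The long noncoding share was 13.9%, 15.1% and 22.4% in replicates 1, 2 and 3. Ribosomal protein genes held 5.82% ± 1.25, genes of the mitochondrial genome 1.34% ± 0.208 and nuclear rRNA genes 0.803% ± 0.377. Replication-dependent histone genes, whose mRNA lacks a poly(A) tail, held 0.00258% ± 0.00104. As shares of TPM, protein-coding genes other than ribosomal protein genes held 41.9%, long noncoding RNA genes 31.9%, the mitochondrial genome 4.84% and replication-dependent histone genes 0.00732%. On the mitochondrial genome mt-Nd6 (overlapped), the protein gene of the light strand, had 18316, 1673 and 13631 counts in replicates 1, 2 and 3, against 10721, 546 and 5027 for mt-Co1 (overlapped) on the other strand.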

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

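The choices that left out genes with an opposite-strand overlap, matched random lists on it, or left out replicate 2 for agreement, lists and shares were made after the data were seen; the others were planned. The lowest correlation between libraries, 0.767, was 0.658 with a pseudocount of 0.1, 0.893 with no filter on low values and 0.914 without replicate 2. On genes with no overlap it was 0.710. The count of varying genes, 3731 of 11595 tested, was 1750 of 5137 at a mean count of at least 100, 1201 of 6933 on genes with no overlap, and ranged from 1332 to 1941 when 1 replicate was left out. Leaving out a replicate moved the coefficient of variation from 0.348 to between 0.297 and 0.469, and genes with no overlap gave 0.256. Of the pairs, 21 of 25 passed where both genes had at least 1 TPM and 18 of 20 where neither was overlapped. Fewer pairs were tested there. Without replicate 1, 7 pairs no longer passed (among them Cxcr3 against Cxcr5, Il12rb2 against Il12rb1, Il4ra and Il23r, and Stat4 against Stat6 and Stat3, where Cxcr5, Il12rb2, Il4ra, Stat6 and Stat3 were overlapped). Cxcr3 against Ccr6 passed without replicate 1 and without replicate 3, and Runx3 against Zbtb7b (overlapped) without replicate 2. The Th1 list passed against 12 lists, against 0 of 6 with members of at least 1 TPM alone, where fewer genes were compared, and its difference from the macrophage list, 4.63, became -0.62 there. Its difference from CD8 T-cell genes passed with a pseudocount of 0.1. Lists outside the random range were 9 of 75, then 5 with matching on overlap, 1 of 72 on genes with no overlap and 6 of 25 without replicate 2. The share counted in long noncoding RNA genes, 17.1% of counts, was 31.9% of TPM. Elsewhere the cause was not tested. Detected genes ranged from 7737 to 11118 over all alternatives. Posterior mean TPM was not run because TPM was computed from counts. No paired analysis of groups was possible because there is 1 group. In replicate 2, 3 counts in a gene of 2000 bp equal 11.6 TPM, so a gene at 0 there can lie well above 1 TPM.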

Other observations

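The bounds on transcription of noncoding genes by themselves, in the correlation across pairs and in the comparison of noncoding genes in exons and introns, were written before the result was seen. The other tests were chosen after the result was seen.

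Noncoding genes that lie opposite to coding exons held more fragments than the coding genes. Gm16008 had 28361 fragments over the 3 libraries and Tnfrsf18 opposite to it 1583, Gm17041 had 12922 and the cytokine signalling gene Cish 1251, and Gm26885 had 12005 and the kinase gene Pim1 1513. Of 500 such pairs, 96.6% had a higher density of fragments in the noncoding gene, with a median ratio of 53.3. Density was all fragments per shared exon base in the noncoding gene, but per base of all exons in the coding gene. This raises the ratio where the noncoding gene extends beyond the overlap, and some noncoding genes stood in more than 1 pair. A library that does not keep strand would divide shared fragments evenly, yet in 80% of the 50 pairs with at least 80% of the noncoding exon bases shared, the coding gene had fewer than 1 fragment for every 2 of the noncoding gene. Transcription of the noncoding genes by themselves was left undecided by a first test, a Spearman's rho of 0.378 across pairs, and a second, added for that reason, found 120.3 times more fragments per kb in noncoding genes sharing exon bases than in those within introns, which argues against it and is what a candidate explanation needs, that the stranded libraries were counted on the strand opposite to the RNA.

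If so, a level in the report may be the small part of a gene's fragments that fell on its annotated strand. In overlapped genes it may also hold fragments of the gene opposite. This reading rests on the 120.3-fold difference and the 80% of pairs above. The higher counts of mt-Nd6 than of mt-Co1 on the other strand, in each library, were not used as a test of it. Values of genes marked as overlapped then cannot be read as levels of those genes, and pairs that hold them share this limit. Among them are Foxp3 (opposite to Ccdc22), Csf1r (opposite to Hmgxb3), Il12rb2 (opposite to Serbp1) and Il21. In any gene, 0 counts then exclude less than the totals imply. Counting the alignments with the other strand setting would test this, and they were not analysed here.

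Replicates 1 and 3 differed by overlap: the median log2 ratio of replicate 3 to 1 was 0.39 in overlapped genes and -0.56 in the others, among genes with a mean count of at least 100. The coding gene's share of the pair's density, on the same unlike divisors, had a median of 2.74%, 2.27% and 1.14% in replicates 1, 2 and 3. It was lower in replicate 3 than in 1 in 93.7% of 490 pairs. A smaller share of fragments on the annotated strand in replicate 3 would give this. Between the classes the gap was 0.95 for replicate 3 over 1, whose totals were 3733531 and 4482916 counts. It was 0.127 for replicate 2 over 1, 16.8-fold apart in depth. These totals and gaps argue against depth as the source of the gap between replicates 1 and 3. The bound set for this test could not be met, as only 1 library was of low depth. No biological explanation was tested, since there is 1 group.

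Xist and Tsix, which overlap on the X chromosome, had 2467, 403 and 20 fragments together in replicates 1, 2 and 3, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty 337, 0 and 339. The low depth of replicate 2 is argued against as the reason for its 0, since 18.6 Y-linked fragments were expected there. The strand share cannot give the 102.7-fold higher level of Xist and Tsix, as a share of the library, in replicate 1 than in 3. Y-linked genes stood in replicate 1 at 57.5% of their level in replicate 3 per fragment of genes without overlap (95% interval 49.3% to 67.1%) and at 82.8% per fragment of the library (71.0% to 96.6%), consistent with cells of both sexes in replicate 1. Whether that came from pooled animals, a mixed library or a wrong label stays open, as the labels give sex as not collected and 1 donor record. Replicate 2 held 403 Xist and Tsix fragments with 0 Y-linked, and replicate 3 held 20 with 339. That argues against 1 animal as the source of both, so the spread between libraries may include sex.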
